A study of Homo sapiens with 6 samples.

How the data were processed

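MCF-7 cells, an estrogen receptor-positive human breast carcinoma line, here carrying a stably expressed eGFP-LC3 autophagy reporter, were transfected with 10 nM of an siRNA against EIF5A or a scrambled control siRNA for 72 h, with fresh medium after 24 h, per the labels' protocols. EIF5A encodes eukaryotic translation factor 5A, the protein that carries the modified amino acid hypusine and helps ribosomes over difficult peptide bonds. Total RNA from 3 biological replicates per group was depleted of ribosomal RNA with Ribo-Zero Gold and made into Illumina TruSeq libraries, per the labels' protocols, so RNAs without a poly(A) tail are retained.

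The authors deposited raw read counts per gene symbol, 1 column per library, for 26215 genes. The submitters' processing notes name cutadapt, Bowtie2 2.2.4, HTSeq and the genome build hg19 without giving their roles. The gene annotation, the handling of reads that map to several places and the strand setting are not given in the sources used here, so genes with near-identical copies and genes overlapping on opposite strands are treated as uncertain. No row holds unassigned reads, and every column was used. The authors also deposited a comparison table for 11400 genes. Per the file headers it holds a mean normalized count (baseMean, a signal averaged over libraries), a log2 fold change, its standard error, a test score (the statistic), a p-value and an adjusted p-value for each gene. The software is not named. The baseMean values equal the mean of the raw counts after median-of-ratios scaling over all 6 libraries, and no gene with a mean at or above the table's smallest baseMean of 21.9 is missing from it.

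The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its usual minimum count of 10 and minimum total of 15, which left 12424 genes. Library sizes were scaled by TMM factors. The knockdown was compared with the control by the quasi-likelihood F test with an intercept and a group term, all 6 libraries entering the fit, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. All p-values for genes in the text come from this test unless another is named. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Expression is given as TMM-normalised CPM, as mean ± SD over 3 libraries.

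A set of 21 gene lists was written before the data were examined, together with the design, the alternative settings and the rule for naming genes. The lists cover hypusination and polyamines, autophagosome formation, autophagy receptors and lysosome, the unfolded protein response, the ATF4 response, p53 targets, mitosis, DNA replication, replication-dependent histones, cholesterol synthesis, estrogen response, ribosomal proteins, translation factors, ribosome biogenesis, nuclear and mitochondrial oxidative phosphorylation genes, hypoxia and glycolysis, interferon response, NF-kB and inflammatory genes, luminal markers, and basal and mesenchymal markers as a check for other cells. The 20 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and p was adjusted over the lists. The 13 mitochondrial transcripts were not analysed here. Members were also counted with p adjusted over the list alone.

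The naming rule took 7 fixed genes (EIF5A, EIF5A2, DHPS, DOHH, ATG3, MAP1LC3B and SQSTM1), the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the groups (unnamed loci, antisense and small RNA symbols left out), and up to 3 called members per list with the smallest adjusted p, at least 1 of them from the minority direction.

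Alternatives set before the data were examined were median-of-ratios and upper-quartile factors, DESeq2 1.42.0, limma-voom, other filters on low counts, the replicate number as a block, each library left out in turn, stricter thresholds, camera with an estimated correlation, and fry. After the data had been seen, a correction for transcript GC content and length, thinning of every library to the smallest total, and removal of the dominant RNAs RPPH1 and RMRP were added. GC content and length came from the longest transcript of each gene in GENCODE release 29, protein-coding transcripts first, matched by symbol for 12171 of the 12424 tested genes (98.0%). The correction removed a loess trend (span 0.5) of each library's log2 deviations on GC content and log2 length as an offset. That annotation is of another genome build than the counts, so no coordinates are given.

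The fits were tested on simulated counts with the real means, library sizes and dispersions and 50 changed genes per fold size among 12361 tested genes. In the simulated comparison of knockdown with control, edgeR recovered 40.0% of genes changed 1.25-fold, 82.0% of those changed 1.5-fold and 98.0% of those changed 2-fold, with 15 false calls. With a GC trend added to the simulated counts (12338 tested genes), edgeR recovered 20.0%, 62.0% and 90.0% at these fold sizes with 8 false calls, and 42.0%, 85.7% and 93.8% after the GC and length correction (12093 tested genes) with 12 false calls. The changed genes were drawn from better-expressed genes only, so recovery of weakly expressed genes was not tested. The dispersions came from the uncorrected fit and already held the GC spread between libraries. The false calls therefore do not show how many a GC trend gives in the real data. A list of 50 genes shifted by 0.25 on the log2 scale was found among 40 unchanged lists, of which 0 were called. This simulation drew genes independently and without a GC trend, so it does not show how often camera calls lists of co-varying genes in error.

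Depth ranged from 5657270 to 13139549 counts per library, so 1 count corresponded to between 0.0761 and 0.177 CPM before scaling. No molecular identifiers are described, so counts are reads rather than distinct molecules.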

Results

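The series asked how the RNA content of MCF-7 cells changes when EIF5A is silenced. It holds 3 control siRNA libraries and 3 EIF5A siRNA libraries of ribosomal RNA-depleted total RNA. The control libraries held 10851767, 5657270 and 8179230 counts and the knockdown libraries 10004498, 13139549 and 11636241 counts. At least 1 count was seen for 17790 of 26215 genes. RPPH1, the RNA component of RNase P, took 14.5%, 10.4% and 12.7% of the counts in the controls and 14.2% in each knockdown library. The libraries of each group differed by more than sampling noise, with a chi-square per gene between 1.83 and 10.5 over the 6 within-group pairs, so none was a copy of another. That each library is its own biological replicate rests on the labels. The p-values of single genes below measure differences against the spread between these replicate libraries. The test draws each gene's spread toward a trend over all genes, so these p-values also rest on the spread of other genes. Those of camera with the preset correlation compare list members with the other tested genes, so they rest largely on the spread over genes.

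EIF5A mRNA fell to 5.24% of the control level. It measured 54.8 ± 4.10 CPM in the controls and 2.83 ± 0.317 CPM in the knockdown libraries (mean ± SD, n = 3 each), a log2 fold change of -4.25 with a standard error of 0.13 (edgeR quasi-likelihood test, adjusted p = 1.1e-16). The raw EIF5A counts were 602, 349 and 418 in the controls against 26, 41 and 30 after knockdown. EIF5AL1, a near-identical copy of EIF5A, had 32, 11 and 18 counts in the controls and 1, 0 and 1 after knockdown. Reads of the pair cannot be told apart with certainty, so no separate change is claimed for it. EIF5A2, the paralog encoding a second hypusinated protein, measured 43.2 ± 3.44 CPM and 49.0 ± 4.23 CPM and did not pass the test (log2 fold change 0.18 ± 0.09 SE, adjusted p = 0.16). The hypusinating enzymes DHPS (log2 fold change -0.16, adjusted p = 0.16) and DOHH (0.24, adjusted p = 0.31) did not pass either. Over the fits that left out 1 library, the log2 fold change of DOHH ran from 0.059 to 0.45. DOHH passed without control replicate 2 (adjusted p = 0.039) and after the correction for GC content and length (adjusted p = 0.025), and its adjusted p ranged from 0.025 to 0.82 over 15 alternative fits. The ranges given for other genes below cover the same alternatives, except that TNFAIP2 had an adjusted p in 14 of them and CXCL8 in 13.

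Among the 14 tested genes of hypusination and polyamine metabolism, 4 rose and 3 fell, and 7 did not pass. ODC1, ornithine decarboxylase, the first enzyme of polyamine synthesis, rose from 152 ± 10.9 to 230.1 ± 7.93 CPM, a 1.51-fold change (log2 fold change 0.60 ± 0.07 SE, adjusted p = 1.7e-05). ATP13A3, a polyamine transporter, rose 1.31-fold (adjusted p = 0.00076). The counts adjusted over the list alone were also 4 higher and 3 lower. The list as a whole was not called by camera (adjusted p = 0.81), and its median log2 fold change of 0.13 and its mean of -0.29, which includes EIF5A itself, differ in sign. The median was 0.034 after the GC and length correction and 0.082 without knockdown replicate 3. With upper-quartile scaling 3 members rose and 3 fell. Over the fits that left out 1 library, 3 to 5 members rose and 1 to 4 fell, with 1 lower without control replicate 2, control replicate 3 or knockdown replicate 1. With GC and length corrected, 5 rose and 2 fell.

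**Figure D1:**
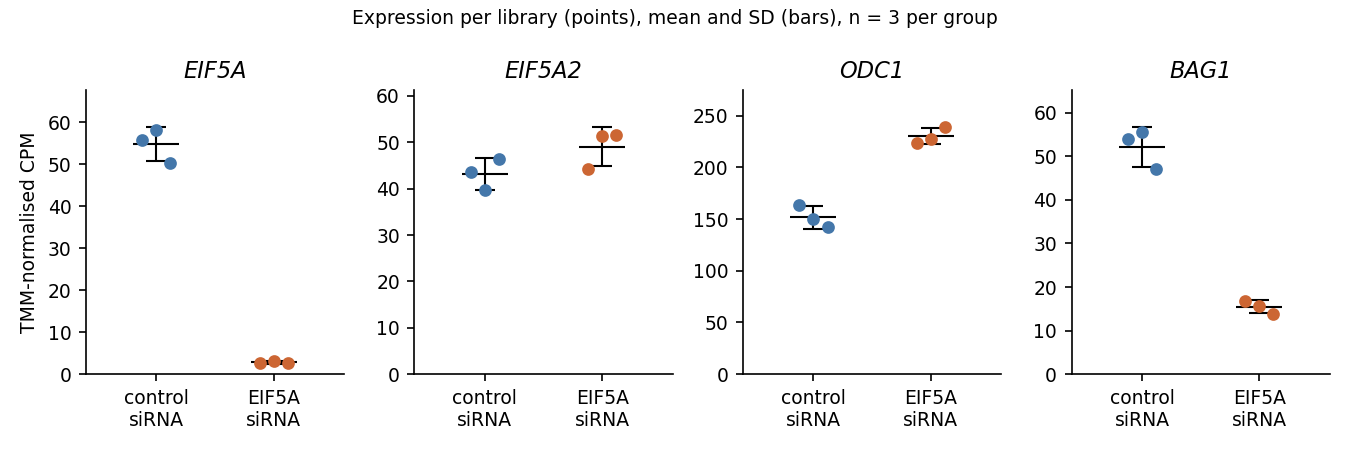
TMM-normalised CPM (y axis, from 0) of EIF5A, EIF5A2, ODC1 and BAG1 in each library (points), with group means and SD (bars), n = 3 per group. EIF5A lies near 54.8 CPM in the controls and 2.83 CPM after knockdown, BAG1 falls from 52.2 to 15.5 CPM, ODC1 rises from 152 to 230.1 CPM, and EIF5A2 overlaps between the groups.

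Beyond the target, the response was broad and shallow. The libraries include no other siRNA against EIF5A and no rescue, so effects of EIF5A loss cannot be told apart from off-target effects of the siRNA. Of 12424 tested genes, 1096 were higher and 990 lower in the knockdown libraries, 16.8% of the genes tested. With upper-quartile scaling the split turned to 805 higher and 1232 lower. The median size of the change was 0.33 on the log2 scale for the genes that rose and 0.42 for those that fell, and 55 genes changed at least 2-fold, 3 of them upwards and 52 downwards. The 3 that rose, CFH, CXCL8 and HIST1H2BB, lay below a mean of 5 CPM. Groups did not overlap for 34.4% of the tested genes, where chance gives 10% on average. Genes share trends between libraries, so the share in any single arrangement of the libraries can lie far from 10% without an effect of the siRNA. Leaving out control replicate 3 lowered the count of changed genes to 1184. Leaving out knockdown replicate 1, 2 or 3 lowered it to 1342, 1000 and 1061.

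Among called genes with a mean of at least 5 CPM and no overlap between the groups, those that fell most after EIF5A encode proteins of varied function. BAG1, a co-chaperone of HSP70 proteins, fell to 29.7% of control, from 52.2 ± 4.53 to 15.5 ± 1.54 CPM (adjusted p = 7.7e-11). UCP2, a mitochondrial carrier protein, fell to 34.0% (38.1 ± 12.9 to 12.6 ± 1.31 CPM, adjusted p = 4.0e-06), SUSD3 to 38.9% and GYG2, a glycogenin that primes glycogen synthesis, to 43.5%. HR, a nuclear receptor corepressor, fell to 45.7% (adjusted p = 4.5e-07). AHNAK2, NLGN2, AFAP1L2 and SOCS2, a suppressor of cytokine signalling, lay between 46.2% and 47.3% of control.

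Under the same limits on expression and overlap, the largest increases were smaller. PCDH9, a protocadherin, rose 1.89-fold (log2 fold change 0.92 ± 0.13 SE, adjusted p = 8.6e-05). TMTC2 and TMTC3, related endoplasmic reticulum mannosyltransferases, rose 1.84-fold (adjusted p = 7.0e-06) and 1.69-fold (226 ± 38.2 to 384 ± 11.8 CPM, adjusted p = 1.2e-05). The adhesion molecule CADM1 rose 1.77-fold, CXXC1, a subunit of a histone methyltransferase complex, 1.75-fold, the netrin receptor UNC5C 1.67-fold and the peptide hormone gene ADM 1.66-fold. KBTBD8, ZNF730 and the heparan sulfate proteoglycan SDC2 rose between 1.61-fold and 1.66-fold. For these 10 genes and the 10 largest decreases, no single library left out ended a call. SDC2 lost its call after thinning to the smallest library (adjusted p = 0.054, range 0.0022 to 0.054).

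The fold changes were related to transcript composition. Across the 12171 genes with a known GC content, the Spearman correlation between log2 fold change and GC content was -0.34, a correlation over genes, which are not independent replicates. In the lowest GC quintile 471 genes were higher and 56 lower, and in the highest quintile 89 were higher and 306 lower. The same trend separated libraries within the control group. The correlation of each library's deviation with GC content was -0.27, 0.57 and 0.26 in control replicates 1, 2 and 3, and -0.16, -0.38 and -0.30 in the knockdown replicates. After correction for GC content and length, 1613 genes were higher and 1252 lower, and 1746 of the 2065 original calls that could be corrected were kept. None of these 2065 calls changed sign.

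**Figure D2:**
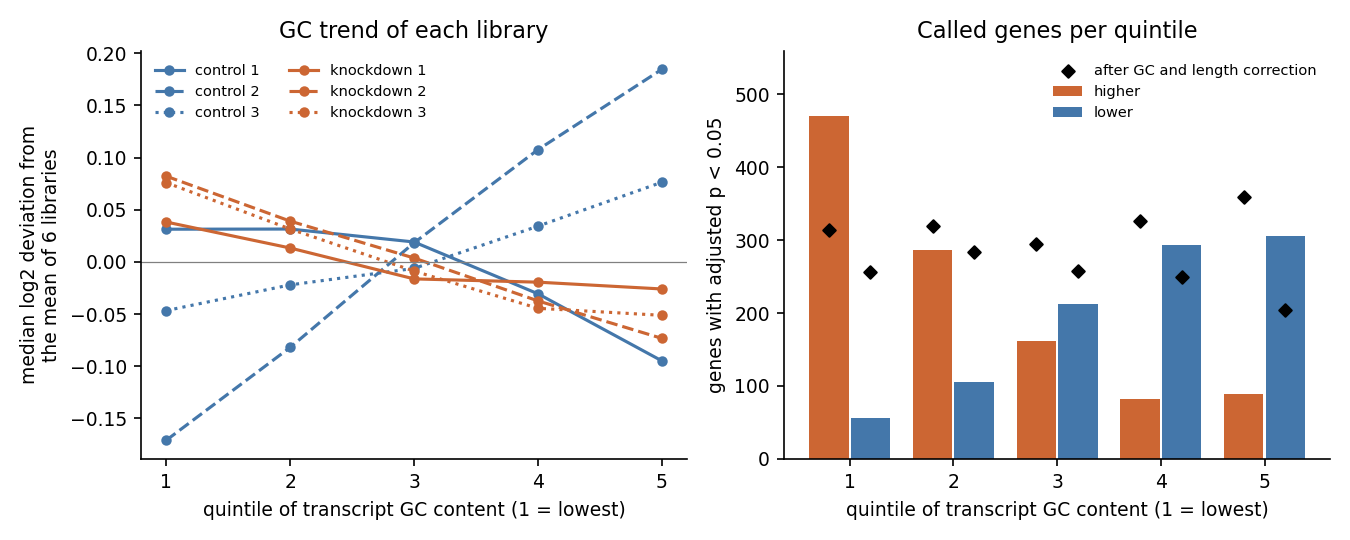
Left, the median log2 deviation of each library from the mean of the 6 libraries (y axis) in 5 equal groups of genes by transcript GC content (x axis, 1 is the lowest), and right, the number of genes called higher (orange bars) and lower (blue bars) per quintile with the counts after GC and length correction (diamonds). Control replicate 2 has the steepest trend, and calls go from 471 higher and 56 lower in the lowest quintile to 89 higher and 306 lower in the highest before correction.

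Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and accumulate in S phase, rose together. Of 51 tested members 27 were higher and 0 lower in edgeR, and adjusted over the list alone 35 were higher. At an unadjusted p below 0.05, 36 were higher and 0 lower, and 0 were lower in DESeq2 or limma-voom. HIST1H3A rose 1.33-fold (229 ± 9.65 to 303 ± 13.3 CPM, adjusted p = 0.00045), HIST1H2AI 1.27-fold (adjusted p = 0.0012) and HIST1H1B 1.30-fold (1602 ± 140.2 to 2084 ± 98.8 CPM, adjusted p = 0.0014). The list median was 0.23 on the log2 scale. Individual histone genes share near-identical sequence, so single members are uncertain, but the summed expression of the family also rose 1.17-fold, from 22887 ± 264 to 26857 ± 1341 CPM, with no overlap between the groups. The list was the only one of 20 called by camera with the preset correlation (adjusted p = 2.0e-10, adjusted p = 0.87 with an estimated correlation), and 39 members were higher after the GC and length correction. Upper-quartile scaling left 22 members higher. Without control replicate 3 there were 19, without knockdown replicate 2 there were 18 and without knockdown replicate 3 there were 11.

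Fewer members of the other cell cycle lists were called; a difference between the lists was not tested. Of 38 DNA replication genes, 5 rose and 1 fell (adjusted over the list alone, 6 and 1). The cyclin gene CCNE2 rose 1.35-fold (adjusted p = 0.0010) and RRM2, the small subunit of ribonucleotide reductase, 1.29-fold (adjusted p = 0.0012), while POLD1, the catalytic subunit of DNA polymerase delta, fell to 65.8% of control (adjusted p = 0.00024). Of 32 mitosis genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone), namely CDK1 (1.26-fold, adjusted p = 0.0052), BIRC5 (1.19-fold, adjusted p = 0.013) and UBE2C (1.18-fold, adjusted p = 0.034). BIRC5 lost its call without control replicate 3 (adjusted p = 0.074), knockdown replicate 2 (0.062) or knockdown replicate 3 (0.096, range 9.8e-05 to 0.096). UBE2C lost it without control replicate 1 (0.078), control replicate 3 (0.099), knockdown replicate 2 (0.14) or knockdown replicate 3 (0.17), with upper-quartile scaling (0.069) and after thinning (0.19, range 0.0025 to 0.19). Across the fits without 1 library, 3 to 7 DNA replication genes rose and 1 to 3 fell (3 and 1 without knockdown replicate 2), and 1 to 5 mitosis genes rose and at most 1 fell (1 higher without control replicate 3 or knockdown replicate 2 or 3). At an unadjusted p below 0.05, 6 mitosis genes were higher and 2 lower in edgeR, and DESeq2 and limma-voom each called 3 higher and 0 lower. With upper-quartile scaling 4 DNA replication genes rose and 4 fell, and 2 mitosis genes rose and 1 fell. After the GC and length correction 9 DNA replication genes rose and 2 fell, and 3 mitosis genes rose and 1 fell. Camera called neither list (adjusted p = 0.21 for both).

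**Figure D3:**
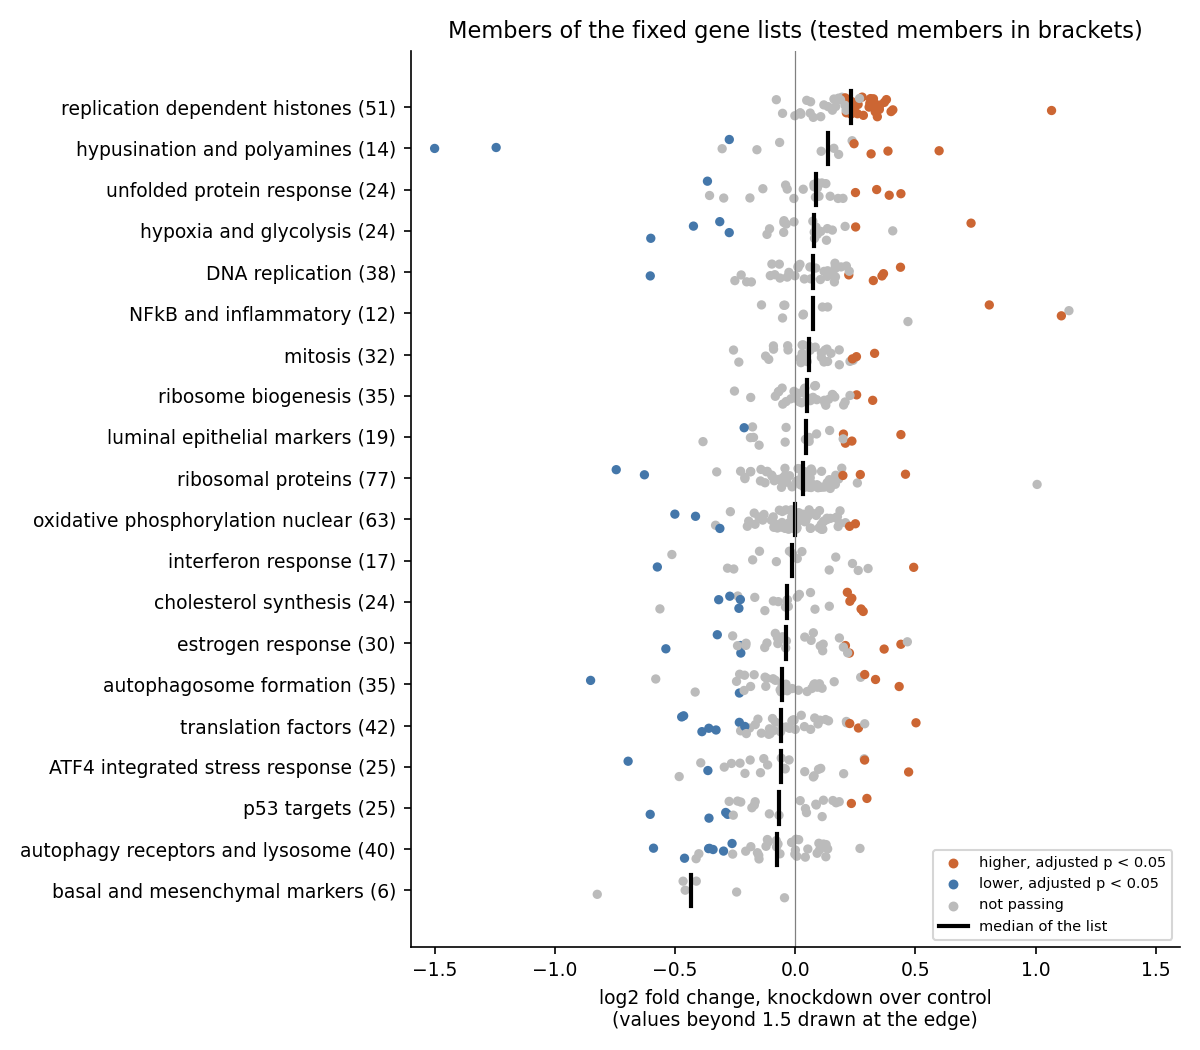
Log2 fold change, knockdown over control (x axis), of each tested member of 20 fixed gene lists (rows, number of tested members in brackets), with members called higher in orange, lower in blue and not passing in grey, and list medians as black bars. The histone list stands furthest to the right by its median of 0.23 with 27 of 51 members called higher, and most other lists hold members on both sides of 0.

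The study's reporter marks autophagy. Most mRNAs of the autophagy machinery did not pass the test, as held for all tested genes, of which 16.8% were called. Of 35 autophagosome formation genes, 3 rose and 2 fell (the same counts adjusted over the list alone), and 30 did not pass. ATG3, the enzyme that conjugates LC3 to lipid, measured 105 ± 7.16 CPM in the controls and 103 ± 4.41 CPM after knockdown (log2 fold change -0.03 ± 0.07 SE, adjusted p = 0.81). MAP1LC3B had a log2 fold change of -0.21 ± 0.12 SE (adjusted p = 0.23); the reads of its transcript and of the eGFP-LC3 reporter may overlap. ULK1, the kinase that starts autophagy, fell to 55.4% of control (22.8 ± 8.70 to 12.1 ± 1.72 CPM, log2 fold change -0.85, adjusted p = 0.0029). Among the controls replicate 2 was highest for ULK1, and without it the log2 fold change was -0.55 (adjusted p = 0.018, range 1.7e-09 to 0.043). ATG5 rose 1.22-fold (adjusted p = 0.0089) and ATG4A 1.35-fold (adjusted p = 0.0097). Without knockdown replicate 3 the calls of ATG5 (adjusted p = 0.052) and ATG4A (adjusted p = 0.059) were lost, as were that of ATG5 without knockdown replicate 2 (adjusted p = 0.068) and that of ATG4A without control replicate 3 (adjusted p = 0.067) and after thinning (adjusted p = 0.067). The adjusted p ranged from 0.0041 to 0.068 for ATG5 and from 0.0026 to 0.067 for ATG4A. Without knockdown replicate 3, 0 members of the list rose and 1 fell; without control replicate 3 or knockdown replicate 2, 1 rose and 1 fell. With GC and length corrected, 6 rose and 3 fell. Upper-quartile scaling gave 3 higher and 3 lower. Camera did not call the list (adjusted p = 0.79).

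Of 40 autophagy receptor and lysosome genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone). The lysosomal thioesterase PPT1 fell to 77.9% of control (627 ± 6.27 to 489 ± 19.6 CPM, adjusted p = 0.00085), the progranulin gene GRN to 72.7% (adjusted p = 0.0060, groups overlapping) and the autophagy receptor NBR1 to 81.3% (adjusted p = 0.0081, and 0.061 without control replicate 3, range 0.00034 to 0.061). The receptor SQSTM1 (p62) stayed within replicate error, at 214 ± 18.8 and 212 ± 2.42 CPM (log2 fold change -0.02 ± 0.07 SE, adjusted p = 0.92). The list was not called by camera (adjusted p = 0.21), and after the GC and length correction 4 members were higher and 8 lower. With each library left out in turn, 3 to 11 members fell (3 without knockdown replicate 1, 4 without control replicate 3 or knockdown replicate 2, 11 without control replicate 1) and 0 rose. At an unadjusted p below 0.05 edgeR had 12 lower and 0 higher, and DESeq2 and limma-voom each called 7 lower and 0 higher. Upper-quartile scaling gave 8 lower and 0 higher.

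Stress response genes moved in both directions. Of 24 unfolded protein response genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone). XBP1, a transcription factor of this response, rose 1.36-fold (1655 ± 21.9 to 2245 ± 91.1 CPM, adjusted p = 0.00018) and the chaperone gene DNAJC3 1.31-fold (adjusted p = 0.0012), while HERPUD1 fell to 77.7% (adjusted p = 0.0036). Of 25 genes of the ATF4 integrated stress response, 2 rose and 2 fell (3 and 5 adjusted over the list alone). DDIT4, an inhibitor of mTORC1 signalling, fell to 61.8% (285 ± 10.4 to 176 ± 9.87 CPM, adjusted p = 2.0e-06) and SHMT2, a mitochondrial enzyme of serine metabolism, to 77.7% (adjusted p = 0.0015), while the amino acid transporter subunit gene SLC3A2 rose 1.22-fold (adjusted p = 0.0048). Of 25 p53 targets, 4 fell and 2 rose (4 and 2 adjusted over the list alone), with BTG2 at 65.8% of control (adjusted p = 3.6e-05), DDB2 at 78.0% (adjusted p = 0.0065) and TRIAP1 1.23-fold higher (adjusted p = 0.0097). TRIAP1 lost its call without control replicate 3 (adjusted p = 0.068) or knockdown replicate 3 (adjusted p = 0.055, range 0.0034 to 0.068). Over the fits that left out 1 library, 3 to 5 unfolded protein response genes rose and 1 to 5 fell (5 fell without control replicate 1). In the ATF4 list 1 to 2 rose and 2 to 6 fell (6 fell without control replicate 1). In the p53 list 0 to 3 rose and 2 to 5 fell (0 rose without control replicate 3 or knockdown replicate 3). After the GC and length correction 8 unfolded protein response genes rose and 1 fell, 3 ATF4 genes rose and 4 fell, and 3 p53 targets rose and 5 fell. Upper-quartile scaling gave 4 higher and 2 lower for the unfolded protein response, 1 and 4 for the ATF4 list and 2 and 4 for p53 targets. Camera called none of these lists (adjusted p = 0.21, 0.47 and 0.53).

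In the translation apparatus, 7 of 42 translation factor genes fell and 3 rose (8 and 4 adjusted over the list alone). EEF2, the translocation factor of elongation, fell to 72.5% of control (6728 ± 455 to 4878 ± 117 CPM, adjusted p = 0.00022), and PABPC1, the main cytoplasmic poly(A)-binding protein gene, to 72.1% (adjusted p = 0.00067), while the initiation factor gene EIF1AX rose 1.42-fold (adjusted p = 0.00037). Of 77 ribosomal protein genes, 2 fell and 3 rose (2 and 1 adjusted over the list alone) and 72 did not pass. RPL13A fell to 59.7% (adjusted p = 2.7e-06) and RPL28 to 64.7% (adjusted p = 0.0050), while RPL35 rose 1.21-fold (adjusted p = 0.0088, and 0.065 without control replicate 3, 0.054 without knockdown replicate 2 and 0.062 without knockdown replicate 3, range 4.7e-05 to 0.065). RPL28 did not pass in DESeq2 (adjusted p = 0.089, range 9.9e-09 to 0.089), and its log2 fold change of -0.63 was -0.35 without control replicate 2 (adjusted p = 0.021), the highest of the controls for this gene. Ribosomal protein genes have many processed pseudogenes that can share their reads. Of 35 ribosome biogenesis genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), PNO1 with a log2 fold change of 0.32 (adjusted p = 0.011) and NOP58 1.19-fold (adjusted p = 0.020). NOP58 lost its call without control replicate 3 (0.086) or knockdown replicate 1 (0.056), 2 (0.069) or 3 (0.097, range 0.0048 to 0.097). Across the fits without 1 library, 4 to 7 translation factors fell and 1 to 6 rose (6 rose and 4 fell without control replicate 1), 2 to 4 ribosomal protein genes fell and 0 to 6 rose (0 rose without knockdown replicate 2 or 3), and 1 to 4 ribosome biogenesis genes rose (1 without control replicate 3 or any knockdown replicate) and 0 to 1 fell (3 rose and 1 fell without control replicate 2). At an unadjusted p below 0.05, 6 ribosome biogenesis genes were higher and 1 lower in edgeR, and DESeq2 and limma-voom each called 2 higher and 0 lower. With GC and length corrected, 13 translation factors fell and 3 rose, 2 ribosomal protein genes fell and 8 rose, and 1 ribosome biogenesis gene fell and 7 rose. Upper-quartile scaling gave 9 lower and 2 higher for translation factors, 3 and 2 for ribosomal protein genes and 1 and 2 for ribosome biogenesis. Camera called none of these lists (adjusted p = 0.47, 0.66 and 0.21).

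Metabolic lists were mixed. Of 24 cholesterol synthesis genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone). FDFT1, squalene synthase, fell to 82.8% (adjusted p = 0.010), SREBF2, the transcription factor of the pathway, to 80.2% (adjusted p = 0.018), and SC5D rose 1.21-fold (adjusted p = 0.022). FDFT1 lost its call without control replicate 3 (0.072) or knockdown replicate 1 (0.060, range 0.0014 to 0.072). SREBF2 lost it without control replicate 2 (0.067) or knockdown replicate 1 (0.068), 2 (0.059) or 3 (0.059, range 0.0028 to 0.068). SC5D lost it without control replicate 2 (0.065), knockdown replicate 2 (0.17) or knockdown replicate 3 (0.059), after the GC and length correction (0.063) and after thinning (0.078, range 0.0087 to 0.17). Without control replicate 2, 0 members of the list rose and 2 fell, and without knockdown replicate 2 or 3, 0 rose and 1 fell. Without knockdown replicate 1, 3 rose and 0 fell, without control replicate 3, 3 rose and 1 fell, and without control replicate 1, 5 rose and 4 fell; upper-quartile scaling gave 1 higher and 5 lower. Of 63 nuclear oxidative phosphorylation genes, 3 fell and 2 rose (3 and 1 adjusted over the list alone), with NDUFA8, a complex I subunit gene, at 75.0% (adjusted p = 0.00073), ATP5D at 70.7% (log2 fold change -0.50, adjusted p = 0.0097, and -0.32 with 0.052 without control replicate 2, range 0.00013 to 0.052) and NDUFA4 1.19-fold higher (adjusted p = 0.025). NDUFA4 lost its call without control replicate 3 (0.11), knockdown replicate 2 (0.17) or knockdown replicate 3 (0.094, range 0.011 to 0.17). With each library left out in turn, 2 to 5 of these genes fell and 0 to 6 rose (0 rose without control replicate 3 or knockdown replicate 2 or 3, and 6 without control replicate 1). Of 24 hypoxia and glycolysis genes, 4 fell and 2 rose (4 and 3 adjusted over the list alone). NDRG1 fell to 65.9% (adjusted p = 0.00015), ADM rose as given above (1.66-fold, adjusted p = 0.0035), and the glucose transporter gene SLC2A1 rose 1.19-fold (adjusted p = 0.019). SLC2A1 lost its call without control replicate 1 (0.051), knockdown replicate 1 (0.071) or knockdown replicate 2 (0.11, range 3.8e-05 to 0.11). Over the fits that left out 1 library, 1 to 3 of this list fell and 1 to 2 rose (1 fell without control replicate 3 or any knockdown replicate). After the GC and length correction 3 cholesterol synthesis genes rose and 2 fell, 7 oxidative phosphorylation genes rose and 6 fell, and 5 hypoxia and glycolysis genes rose and 3 fell. Upper-quartile scaling gave 1 higher and 4 lower for oxidative phosphorylation and 2 and 4 for hypoxia and glycolysis. Camera called none of these lists (adjusted p = 0.79, 0.93 and 0.81).

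Hormone response and cell identity genes moved in both directions. Of 30 estrogen response genes, 4 rose and 4 fell (7 and 7 adjusted over the list alone), with XBP1 1.36-fold higher, CA12, a carbonic anhydrase gene, 1.29-fold higher (adjusted p = 0.0011) and IGFBP4 at 79.9% of control (adjusted p = 0.018). IGFBP4 lost its call without control replicate 3 (0.091) or knockdown replicate 1 (0.10) and after the GC and length correction (0.066, range 0.0025 to 0.10). Across the fits without 1 library, 2 to 5 members rose and 0 to 6 fell (0 fell without knockdown replicate 1, and 1 without control replicate 3 or knockdown replicate 2). The list's median of -0.04 and the direction of its test differ in sign (camera adjusted p = 0.86), and the median was 0.017 without control replicate 2 and 0.046 after the GC and length correction. Upper-quartile scaling gave 2 higher and 6 lower for this list and 2 higher and 2 lower for the luminal markers described next. Of 19 luminal markers, 4 rose and 1 fell (5 and 2 adjusted over the list alone), among them CLDN7, a tight junction gene, 1.18-fold higher (adjusted p = 0.023) and AGR2 at 86.3% (adjusted p = 0.037). CLDN7 lost its call without control replicate 3 (0.079), knockdown replicate 2 (0.13) or knockdown replicate 3 (0.12) and after thinning (0.057, range 5.7e-05 to 0.13). AGR2 lost it without control replicate 3 (0.089) or knockdown replicate 1 (0.20), 2 (0.084) or 3 (0.098) and after thinning (0.060, range 0.00025 to 0.20). With each library left out in turn, 1 to 5 luminal markers rose and 0 to 5 fell (1 rose without control replicate 3 or knockdown replicate 2 or 3, and 5 fell without control replicate 1). The camera adjusted p of the luminal list was 0.53. Of 22 basal and mesenchymal markers, 6 were expressed highly enough to be tested and 0 passed, over all genes or over the list alone. These 6 all had negative log2 fold changes, with a median of -0.43 (camera adjusted p = 0.21), and 2 of them passed without control replicate 1. With no filter on low counts 17 members were included, with a median of -0.16. At an unadjusted p below 0.05, 1 of the 6 was lower in edgeR, and 0 passed in DESeq2 or limma-voom. With GC and length corrected, 6 estrogen response genes rose and 3 fell, 7 luminal markers rose and 1 fell, and 0 basal and mesenchymal markers passed.

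Transfected RNA can trigger innate immune genes. Both groups were transfected with siRNA, so the comparison cannot show whether transfection did so. The tests covered 17 of 31 interferon response genes and 12 of 22 NF-kB and inflammatory genes. For scale, 16.8% of all tested genes were called. Of 17 tested interferon response genes, 1 rose and 1 fell (the same adjusted over the list alone). IFI6 rose 1.41-fold (11.2 ± 2.85 to 15.5 ± 2.81 CPM, adjusted p = 0.036), overlapping between the groups, and IFI35 fell to 67.2% (adjusted p = 0.027). IFI6 lost its call without control replicate 1 (0.054), control replicate 3 (0.20), knockdown replicate 1 (0.17) or knockdown replicate 2 (0.076), and with upper-quartile scaling (0.057), DESeq2 (0.061) and thinning (0.075, range 0.0039 to 0.20). IFI35 lost it without control replicate 2 (0.073), control replicate 3 (0.052) or knockdown replicate 2 (0.22, log2 fold change -0.35 against -0.57), and with DESeq2 (0.057) and thinning (0.051, range 0.0040 to 0.22). Of 12 tested NF-kB and inflammatory genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone). These were TNFAIP2 (1.80 ± 0.763 to 3.24 ± 0.395 CPM, adjusted p = 0.040) and the chemokine gene CXCL8 (0.606 ± 0.198 to 1.41 ± 0.233 CPM, adjusted p = 0.046), both near the lower limit of expression. TNFAIP2 kept its call without control replicate 3 alone, with 0.13 without control replicate 1 or 2, 0.11 without knockdown replicate 1, 0.058 without knockdown replicate 2 and 0.12 without knockdown replicate 3, and lost it with upper-quartile scaling (0.052) and thinning (0.23, range 0.011 to 0.23). CXCL8 kept its call without control replicate 1 alone, with 0.11 without control replicate 2, 0.17 without control replicate 3, 0.14 without knockdown replicate 1, 0.075 without knockdown replicate 2 and 0.12 without knockdown replicate 3, and lost it with upper-quartile scaling (0.054), without a filter (0.063) and after the GC and length correction (0.075, range 0.030 to 0.17). At an unadjusted p below 0.05, 3 of the 12 were higher and 0 lower in edgeR, DESeq2 called 0, and limma-voom called 3 higher and 0 lower. After the GC and length correction 2 interferon response genes rose and 1 fell, and 3 NF-kB and inflammatory genes rose and 0 fell. Upper-quartile scaling gave 0 higher and 1 lower for the interferon list and 0 called for the NF-kB list. Camera called neither list (adjusted p = 0.92 and 0.21).

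The authors' deposited table does not name its direction, and EIF5A, at a log2 fold change of -3.21, sets it as knockdown over control. Read so, the authors' deposited table lists 912 genes higher and 603 lower at an adjusted p below 0.05, with ATG3 at -0.026. Of the 1515 calls of the authors' deposited table, 1483 were also called in the edgeR fit, all with the same sign, and 98.7% of the 11400 genes of the authors' deposited table had the same sign in both. In the other direction, 603 of the 2086 edgeR calls were not called in the authors' deposited table, and 46 of these genes were absent from it. These values come from the same libraries and are not independent. Over the genes called in both, the fold changes of the authors' deposited table had a median of 0.914 times those of the edgeR fit.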

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

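The GC and length correction, the thinning and the removal of RPPH1 and RMRP were chosen after the data had been seen. No called result changed direction under any alternative. EIF5A stayed between -4.36 and -4.16 on the log2 scale in all 16 other fits, all past the threshold. Median-of-ratios factors, upper-quartile factors, limma-voom, both other filters, DESeq2 and removal of RPPH1 and RMRP kept the count of changed genes between 1579 and 2299 against 2086. The stricter thresholds moved it to 870 genes (473 higher, 397 lower) at an adjusted p below 0.01, and to 55 (3 higher, 52 lower) with a change of at least 2-fold. Leaving out each library gave 1000 to 2899 changed genes (506 to 1465 higher, 494 to 1434 lower), 11 to 31 histone genes higher, and 901 to 1449 calls shared with the authors' deposited table. The replicate numbers did not pair the samples: the correlations of their deviations were -0.13, -0.031 and -0.055 and no control library correlated best with its own number. With the replicate number as a block 1625 genes were called (804 higher, 821 lower), and UBE2C (0.072), NDUFA4 (0.060), CLDN7 (0.064) and AGR2 (0.091) had an adjusted p above 0.05. The ranges given for single genes and symbol families leave this fit out. The number of lists called fell from 1 to 0 with an estimated correlation. It rose to 3 with fry, which added p53 targets (lower) and NF-kB and inflammatory genes (higher), each at an adjusted p of 0.020. The histone list was called by camera in all other 16 fits (adjusted p between 3.0e-17 and 6.5e-08), all with the preset correlation. At that setting camera also called up to 6 lists in splits of the libraries that mix the groups, given at the end. These 16 calls therefore do not test the setting itself. Of 70 called named genes, 49 kept their call without each library and 21 lost it without at least 1. Among uncalled genes the sign turned for ATG3 without control replicate 1 (from -0.084 to 0.014 over the fits without 1 library) and for SQSTM1 without control replicate 3 (-0.085 to 0.044) and after the GC and length correction (0.092). Thinning to the smallest library left 1557 changed genes, so depth limited the number of calls. The causes of the other moves were not tested.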

Other observations

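All tests of explanations in this part were chosen after the results had been seen, except the split counts for histone genes and for gene lists; the thinning test of depth was added after the data had been seen, before its own result was known. The symbol families, grouped by the letters before the first digit of the gene symbol, were also chosen after seeing the data. Of 146 families with at least 10 tested genes, 6 were called by camera with the preset correlation, and with an estimated correlation none was (adjusted p = 0.94 or above). Of 444 ZNF genes, mostly encoding zinc finger transcription factors, 97 rose and 10 fell (median log2 fold change 0.16, adjusted p = 1.8e-07). These transcripts are poor in GC, with a median of 43.4%, and after the GC and length correction 101 rose and 16 fell (median 0.12, adjusted p = 8.5e-05). Of 37 ZBTB genes, another zinc finger family, 9 rose and 0 fell in edgeR (12 and 0 at an unadjusted p below 0.05, 8 and 0 in DESeq2, 9 and 0 in limma-voom; median 0.15, adjusted p = 0.024, 0.028 after correction, and not called after thinning (0.055) or without control replicate 1 (0.075), range over 15 alternative fits 0.012 to 0.075). Without knockdown replicate 2 or 3, 60 and 58 ZNF genes rose, and without control replicate 3, 67 rose, with the ZNF family still called. Without control replicate 2, 78 ZNF genes rose and 5 fell. The PCDHA protocadherins had 2 of 11 higher and the SH family 6 of 26 lower with 1 higher (adjusted p = 0.038 for both), and neither passed after the correction (adjusted p = 0.066 for both). Without control replicate 2, 1 PCDHA gene was higher. PCDHA also lost its call in DESeq2 (0.27), in limma-voom (0.15), without control replicate 1 (0.12) and after thinning (0.056, range 0.0092 to 0.27), and SH without control replicate 1 (0.075), without control replicate 3 (0.056) and after thinning (0.055, range 0.019 to 0.075).

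The HSPA family, which encodes HSP70 chaperones, had 7 of 12 members higher and 0 lower in edgeR, at an unadjusted p below 0.05, in DESeq2 and in limma-voom, although camera did not call it (adjusted p = 0.10, and 0.0033 in DESeq2, 0.020 in limma-voom and 0.019 without control replicate 3, range 0.0033 to 0.26). Without control replicate 2, knockdown replicate 1 or knockdown replicate 3, 4 members rose, and without knockdown replicate 2, 3 rose. HSPA8, the constitutive cytosolic member, had a log2 fold change of 0.50 ± 0.07 SE (adjusted p = 6.4e-05), and HSPA1A one of 0.47 ± 0.09 SE (adjusted p = 0.00086), though HSPA1A and HSPA1B are near-identical and share reads. HSPA5, the endoplasmic reticulum member, did not pass (-0.04 ± 0.07 SE, adjusted p = 0.75). Among 10 factors of nonsense-mediated decay, the pathway that removes mRNAs with premature stop codons, SMG5 (0.61 ± 0.07 SE, adjusted p = 1.2e-05), UPF2 (0.38, adjusted p = 0.0011) and UPF1 (0.30, adjusted p = 0.013, and 0.089 without knockdown replicate 1) rose and 0 fell in edgeR, DESeq2 or limma-voom (1 at an unadjusted p below 0.05), and SMG1 was lower after the GC and length correction (-0.17, adjusted p = 0.026). Without correction SMG1 did not pass (-0.16, adjusted p = 0.13). These genes were picked after their values were seen.

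The fall of log2 fold change with GC content (Spearman correlation -0.34 over genes) was weighed first. A GC bias that varies from library to library is consistent with the controls, where the log2 ratio of replicates 2 and 1 correlated with GC at 0.62, more strongly than the group contrast. For a difference in depth, thinning every library to 5657270 counts left the correlation at -0.37, which argues only against an effect of read sampling. Thinning keeps each gene's expected share of a library, so it cannot test other links between depth and the GC trend. Over the 6 libraries, the correlation with GC content fell at each step up in total counts. It was 0.57 in control replicate 2 (5657270 counts) and -0.38 in knockdown replicate 2 (13139549 counts). A response to EIF5A knockdown that depends on GC content stays open, because the knockdown libraries correlated with GC at 0.0032 against control replicate 1, at -0.53 against replicate 2 and at -0.33 against replicate 3. The 3 controls disagree too much among themselves to decide it.

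The rise of the replication-dependent histone genes was weighed next. The GC trend is argued against by its direction. Genes with HIST symbols are rich in GC (median 57.5%), and in that GC quintile 82 genes were higher and 294 lower. The GC part of the correction was therefore bound to raise them. The list stayed called after it (camera adjusted p = 1.1e-10) with 39 members higher against 27 before, which adds no support. Over all genes of that quintile the number higher also went from 82 to 326. Better recovery of RNA without a poly(A) tail in the knockdown libraries cannot be told apart from a change in the cells: the 199 snoRNA genes had a median of -0.036 ± 0.022 SE, below 0.5 of the histone median (0.12), but the 17 genes annotated as scaRNA, with a median of 0.11 ± 0.047 SE, lay at that bound, and the 23 genes with SCARNA symbols, with a median of 0.17, lay above it. The SE of these medians, and of those given below, is taken over genes, which are not independent replicates, and not over libraries. Of the 2 dominant RNAs, RMRP went the other way, at 1.63%, 1.79% and 1.76% of counts in the controls and 1.47%, 1.29% and 1.27% after knockdown. The share of RPPH1 after knockdown lay within the range of the controls. A larger share of cells in S phase stays open as well, because the DNA replication list had a median of 0.075 ± 0.040 SE and was not called (adjusted p = 0.21). A biological cause tied to EIF5A loss is therefore a hypothesis that these data leave open.

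The SNHG genes, non-coding hosts of small nucleolar RNAs, fell together, with 8 of 16 lower, 0 higher in edgeR (also 0 higher at an unadjusted p below 0.05, in DESeq2 and in limma-voom) and a median log2 fold change of -0.28 (adjusted p = 0.0040, and 0.96 with an estimated correlation). The family lost its call without control replicate 1 (adjusted p = 0.070, 7 lower, range over 15 alternative fits 0.00019 to 0.070), and 5 members fell without knockdown replicate 1 or 3. SNHG7 (-0.77 ± 0.10 SE), SNHG17 (-0.80 ± 0.13 SE) and SNHG8 (-0.51 ± 0.08 SE) were among them, and of other host genes picked after seeing their values, GAS5 (-0.54 ± 0.09 SE, adjusted p = 0.00046) and ZFAS1 (-0.47 ± 0.08 SE, adjusted p = 0.00039) also fell. The GC trend is argued against, since after the correction the median was -0.34 and 8 members were lower (camera adjusted p = 0.0049 with the preset correlation). A change in nonsense-mediated decay stays open: the spliced host RNAs are targets of this pathway, but the 8 called lower are the pattern itself and decide nothing, and the rise of SMG5, UPF2 and UPF1 mRNA does not give the activity of the pathway. A general loss of RNAs that begin with an oligopyrimidine tract is argued against by the ribosomal protein genes, which carry it and had a median of 0.032 ± 0.029 SE (-0.0014 with upper-quartile scaling and -0.018 without control replicate 3), although pseudogenes can share their reads. A loss limited to some of these RNAs stays open, since RPL13A (-0.74, adjusted p = 2.7e-06), EEF2 (-0.46, adjusted p = 0.00022) and PABPC1 (-0.47, adjusted p = 0.00067), whose RNAs carry the tract too, also fell, and 7 translation factors fell and 3 rose. Whether any of these 3 genes hosts small nucleolar RNAs itself was not examined. Their fall therefore does not separate a loss tied to the tract from one tied to host genes. A change in transcription or stability of these hosts after EIF5A loss may remain as a hypothesis, untested here.

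The 6 libraries can be split into 10 pairs of groups of 3, too few for a share under 0.05. The real split gave 2086 changed genes and the highest of the others 3, and 1 of the 10 splits, the real one, gave as many. It gave 27 histone genes in the same direction against 0 in any other split, so again 1 of 10. Every other split mixes control and knockdown libraries, so a difference between the real groups widens the spread within its sides and holds calls down. The size of these gaps therefore adds nothing to the 1 of 10. For gene lists called by camera the real split gave 1 and the highest of the others 6, and 8 of the 10 splits gave at least as many. With the preset correlation, the number of lists called therefore does not set the real split apart. The camera p-values for lists and symbol families at that setting are to be read with this limit.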
